A study of Mus musculus with 42 samples.

How the data were processed

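The series profiled RNA of dorsal root ganglion (DRG) and nodose ganglion (NG) of BALB/c mice, an inbred laboratory strain, on Affymetrix GeneChips, on which each transcript is read by a probe set of short oligonucleotides. The DRG holds the cell bodies of spinal sensory neurons, and the NG holds those of vagal afferents from the viscera. There were 3 experiments and 6 groups. In the first, whole ganglia were lysed (DRG n = 5, NG n = 7, MG-U74Av2 arrays). In the others, about 150 neurons per sample were collected by laser capture microdissection, which cuts chosen cells from a tissue section, and hybridized to MG-U74Av2 (DRG n = 5, NG n = 5) or to Mouse430_2 arrays (DRG n = 9, NG n = 11). About 12 µg of RNA was labelled per sample, which the labelling protocol calls amplified RNA for captured neurons on MG-U74Av2 and total RNA for the other experiments. It is not stated how about 150 captured neurons gave that much total RNA for Mouse430_2, so whether that RNA was amplified stays open. The series title and design call the captured cells visceral sensory neurons; how they were recognised is not given in the sources used here. The sample descriptions call all samples laser captured, but the extraction protocol of the first experiment names whole ganglia, and that protocol and the design text were followed. Samples were placed in groups by their titles, which also carry a sample number. Nothing in the labels says that samples came from separate animals, so p-values measure only the spread between these samples, which may be technical.

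The deposited values are signal intensities on a linear scale, 1 per probe set and array, made by the authors with MAS5 per the submitters' processing notes; its version is not given in the sources used here. MAS5 summarises the perfect-match and mismatch probes of a probe set into 1 signal. Deposited values ran from 0.137 to 14677.4 on MG-U74Av2 and from 0.107 to 9923.83 on Mouse430_2. The mean of each array after trimming 2% at each end ranged from 174.9 to 408.3 in whole ganglia, from 187.7 to 274.5 in captured neurons on MG-U74Av2 and from 84.24 to 200.5 on Mouse430_2. These means differed by more than the 10% tolerance, so the deposited intensities were taken as not scaled between arrays, and each array was scaled to the same 2% trimmed mean within its experiment. Detection calls were not analysed here, so a low signal may be background, and the number of arrays limits the precision.

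MG-U74Av2 held 12488 probe sets, of which 66 were controls, and Mouse430_2 held 45101, of which 64 were controls. In the platform annotation, 10855 probe sets of MG-U74Av2 had 1 gene symbol, 396 had several and 1237 had none. On Mouse430_2 the numbers were 34958, 932 and 9211. Gene names were taken only from probe sets with 1 symbol, which gave 8252 and 18194 genes. Entrez identifiers of 10839 and 34754 probe sets were found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed updating. That table served for names only, and no coordinates were used.

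Signals were analysed as log2(signal + pseudocount). The pseudocount was the 20th percentile of all values of an experiment: 11.7 in whole ganglia, 11 in captured neurons on MG-U74Av2, 7.48 on Mouse430_2, and 11.4 where whole and captured arrays on MG-U74Av2 were fitted together. Fold differences are on this scale, which understates differences of dim genes. A probe set was tested if its signal lay above the 40th percentile of its own array on at least as many arrays as the smaller group held; controls were left out. Each experiment was fitted on its own arrays with limma 3.58.1 (lmFit, and eBayes with trend and robust) in R 4.3.3, with the data.table package (version 1.17.8) for reading files. All tests were two-sided unless stated, differences are NG minus DRG, and p-values were adjusted by Benjamini-Hochberg over the probe sets tested, with a threshold of 0.05. A joint limma fit of the 4 groups on MG-U74Av2 gave captured against whole within each ganglion, and the difference between the ganglion differences (interaction).

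The groups, comparisons, gene lists and the rule for named genes were fixed before the data were examined, as were the alternatives apart from the fit named below as added. Some tests of explanations were chosen later and are named as such beside their results, as are genes named outside the rule. Per experiment, the rule named up to 8 genes per direction with the largest log2 difference among those past the threshold whose groups did not overlap and whose higher group lay above the median signal of the probe sets tested. It also named up to 3 members per direction of each gene list past the threshold, a set of fixed sensory genes wherever measured, and any Hox gene. Where a gene had several probe sets, the one with the highest mean log2 signal is given, and disagreement is stated. Some of the fixed genes are not reported here. Of the others, Prdm12 and Calca had no single-gene probe set on either array, and P2rx2, P2rx3, Trpv1 and Htr3b had none on MG-U74Av2. There, Phox2a, Runx1, Ntrk2 and Gfra1 stayed below the filter in both experiments, as did Ret in captured neurons.

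There were 33 gene lists, each tested with camera (limma) for whether its members ranked apart from the other genes, with the correlation between members estimated from the residuals and, beside it, preset at 0.01. A list was tested with 4 or more measured members, and adjusted over the lists. Counts of list members past the threshold use the adjustment over all probe sets; counts adjusted over the list alone stand beside them where they differ. Differences were compared between experiments across genes measured in both. A sample number was tested as a pairing by correlating, across genes, the deviations of same-numbered arrays from their group means. RNA quality was measured by the 3 prime over 5 prime log2 ratios of the Gapdh and beta actin control probe sets and by the trimmed mean, with exact permutation tests between ganglia. Permutation tests that could not be enumerated used 100000 draws.

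The scripts were tested on simulated data drawn from the real arrays' means and spreads, with seeded changes. Each probe set was drawn independently, so the shares, false calls and list results below do not cover correlation between genes or array-wide effects. In whole ganglia (7663 probe sets), 40.6% of 1.41-fold, 93.5% of 2-fold and 100% of 4-fold changes were called, with 8 false calls. In captured neurons the shares were 13.4%, 71.4% and 95.2% on MG-U74Av2 (7499 probe sets, 5 false calls) and 21.9%, 73% and 100% on Mouse430_2 (27878 probe sets, 11 false calls). A shifted gene list was called in each of the 3 simulations; on Mouse430_2, 1 of 32 lists without a shift was also called.

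Alternatives were quantile normalization, the same median on every array, no pseudocount or the 40th percentile as pseudocount, no filter or one at the 60th percentile, eBayes without trend or robust, array weights, the Gapdh ratio as a covariate, the sample number as a fixed or random block, a threshold of at least 2-fold, the joint fit, and each array left out in turn. For the lists, camera with the preset correlation, fry, and the mean over all probe sets of a gene were also run. After the data were seen, the fit on Mouse430_2 of only the sample numbers absent from MG-U74Av2 was added.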

Results

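Gene expression was measured in sensory ganglia of BALB/c mice as array signal intensity, in 3 experiments that each set nodose ganglion (NG), the ganglion of vagal afferents, against dorsal root ganglion (DRG), the ganglion of spinal afferents. Whole ganglia gave 5 DRG and 7 NG samples on MG-U74Av2 arrays, captured visceral neurons gave 5 and 5 samples on the same array type, and captured neurons gave 9 DRG and 11 NG samples on Mouse430_2, of which 5 DRG and 5 NG carry a sample number that also occurs on MG-U74Av2. After the filter on dim probe sets, 7698 probe sets (62% of those on the array, 5897 genes), 7583 (61%, 5784 genes) and 28107 (62.4%, 13973 genes) were tested. Between the ganglia, none of the 9 comparisons of control-probe ratios and array brightness passed Benjamini-Hochberg adjustment. With 5 against 5 arrays on MG-U74Av2, a single such comparison could not pass on its own, so equal RNA quality is not shown there. The lowest p was for the beta actin 3 prime over 5 prime log2 ratio of captured neurons on MG-U74Av2, 5.82 ± 0.23 in NG and 5.45 ± 0.18 in DRG (SD, n = 5 each, exact permutation p = 0.0238, adjusted p = 0.214). On Mouse430_2 that ratio was similar, 5.71 ± 0.37 in NG and 5.61 ± 0.27 in DRG. Whole ganglia lay lower, at 2.94 ± 0.4 and 2.8 ± 0.08.

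The first comparison asked how whole NG differed from whole DRG. Ddc, which encodes the decarboxylase that makes dopamine and serotonin, was 32.9-fold higher in NG, with a signal of 1577 ± 331.2 (SD, n = 7) against 36.47 ± 11.17 in DRG (SD, n = 5; log2 difference 5.04, SE 0.161, adjusted p = 5.76e-13). The proton-sensing receptor Gpr65 was 23.4-fold higher, the synaptotagmin Syt17 19-fold, and the receptors Crhr2 (for urocortins) and Ntsr1 (for neurotensin) 15.1-fold each. Htr3a, a subunit of the serotonin-gated 5-HT3 channel, was 8.09-fold higher in NG, at 4431 ± 544.2 against 536.6 ± 57.1 (log2 difference 3.02, SE 0.102, adjusted p = 7.7e-13). In the other direction, DRG held more Prkcq, a protein kinase C, at 1728 ± 158.2 against 109 ± 37.7 in NG (log2 difference -3.90, SE 0.175, adjusted p = 2.54e-11), and more Mobp, a myelin-associated protein, at 298.8 ± 156.1 against 3.434 ± 1.365 (log2 difference -4.20, SE 0.257). The kainate receptor subunit Grik1 (-2.78, SE 0.237), the water channel Aqp1 (-2.75, SE 0.205) and Pla2g7, the enzyme that degrades platelet-activating factor (-2.95, SE 0.171), were likewise higher in DRG. For each of these genes the 2 groups' values did not overlap, which the rule required of those named for the largest differences. Of all 2727 probe sets past the threshold, 1387 showed no overlap. The caveolar protein Cavin2 (log2 difference 3.09, SE 0.145) and the skeletal myosin light chain Myl1 (3.08, SE 0.182) were also higher in NG. Baiap2l1 (-3.50, SE 0.201), the G protein subunit Gna14 (-2.71, SE 0.216) and Ly86 (-2.65, SE 0.213) were higher in DRG.

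The fixed gene lists in whole ganglia held members of both directions. Of 9 measured genes of small-diameter nociceptors, 6 were higher in DRG and 2 in NG. The DRG-higher ones included Gfra3, the receptor subunit for artemin (197.5 ± 77.43 in NG, 468 ± 71.94 in DRG, log2 difference -1.26, SE 0.203), Tac1, the substance P precursor (-1.12, SE 0.191), and Scn10a, the sodium channel of nociceptors (-0.54, SE 0.104). Of 9 genes of large-diameter afferents, 6 were higher in DRG and 0 in NG, and of 8 receptors for neurotrophic factors the counts were 4 and 0, led by Osmr, a subunit of the oncostatin M receptor (-1.94, SE 0.137). With an estimated correlation, camera gave an adjusted p of 0.177 to each of these 3 lists, against 0.0102, 0.00182 and 0.00721 with the preset correlation. Among 8 factors of the epibranchial placode and visceral reflex circuits, 3 were higher in NG (4 when adjusted over the list alone) and 0 in DRG, led by Tbx3 (log2 difference 1.69, SE 0.146); adjusted p = 0.221 with an estimated correlation. Another of the 3 was Sox2, which is also in the list of satellite glia and Schwann cells. No difference was called for Ntrk3 (-0.12, SE 0.24, adjusted p = 0.733) or for the GDNF receptor Ret (-0.14, SE 0.231, adjusted p = 0.693). Cckar, the cholecystokinin receptor of vagal afferents, was 4.3-fold higher in NG (1898 ± 234 against 434.3 ± 73.01), and Trpc4 (1.84, SE 0.163) and the AMPA receptor subunit Gria2 (1.51, SE 0.14) were also higher there. Shox2 (-2.23, SE 0.18), a homeobox factor, and Ina (-1.78, SE 0.117), a neuronal intermediate filament, were higher in DRG. Of 39 subunits of the mitochondrial respiratory chain, 18 were higher in NG and 2 in DRG, with Uqcrq (0.98, SE 0.165), Ndufa9 (0.97, SE 0.128) and Atp5o (0.82, SE 0.124) at the top; adjusted p = 0.683 with an estimated correlation and 0.0412 with the preset one.

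Some markers of other cells also differed between the whole ganglia. Of 13 endothelial and mural genes, 6 were higher in NG and 2 in DRG, with Eng, an endothelial co-receptor, at 752.8 ± 251.8 in NG and 376.2 ± 68.45 in DRG (0.93, SE 0.205). Of 13 macrophage and lymphocyte genes, 5 were higher in NG (6 when adjusted over the list alone) and 0 in DRG, including the complement gene C1qa (1.22, SE 0.237) and the class II gene H2-Aa (1.12, SE 0.201). Of 13 genes of satellite glia and Schwann cells, 3 were higher in NG, among them Sox2 (0.86, SE 0.127), and 1 in DRG, S100b (-0.82, SE 0.115). Camera called none of these lists. With an estimated correlation the adjusted p was 0.694 for the endothelial and glial lists and 0.683 for the macrophage list. Of 8 blood and skeletal muscle genes, which do not include Myl1, 1 was higher in NG and 1 in DRG (adjusted p of the list 0.92). The former was the troponin Tnnc2 (0.95, SE 0.305, adjusted p = 0.0233). Its difference was 0.84 without DRG array 084 (adjusted p = 0.0629) and 0.91 without DRG array 019 (adjusted p = 0.0543). The muscle actin Acta1 was not called (422.8 ± 426.1 in NG, 117.9 ± 49.01 in DRG, adjusted p = 0.094). It was called with array weights (adjusted p = 0.042) and when all 4 groups were fitted together (0.0193).

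Some genes of the immediate early response and of dissection stress also differed. In whole ganglia 6 of 17 were higher in NG (7 over the list alone), among them Ier2 (1.05, SE 0.137) and Fos (0.92, SE 0.193). In DRG 3 were higher, among them the heat shock gene Hspa1b (-1.36, SE 0.194) and the transcription factor Jun (-0.91, SE 0.209). Jun was also higher in DRG in captured neurons on MG-U74Av2 (-2.78, SE 0.164) and on Mouse430_2 (-1.79, SE 0.125), and Hspa1b on Mouse430_2 (-1.33, SE 0.264). Of 16 such genes on MG-U74Av2, 1 was higher in NG and 2 in DRG (2 and 3 over the list alone), and of 17 on Mouse430_2, 0 and 3. With an estimated correlation the adjusted p of the list was 0.694, 0.743 and 0.408 in the 3 experiments.

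In whole ganglia, limma called 1508 probe sets higher in NG and 1219 higher in DRG, 35.4% of those tested, of which 198 and 160 differed by at least 2-fold. The direction of the total depended on the scaling: NG took 55.3% of the calls, 49.9% after quantile normalization (1341 against 1347) and 40% with the same median on every array (1020 against 1532), a scaling that shifted the median of all probe sets by -0.103. NG array 073 lay apart from the other 6 NG arrays on the first principal component, and without it the counts were 1600 and 1304.

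**Figure D1:**
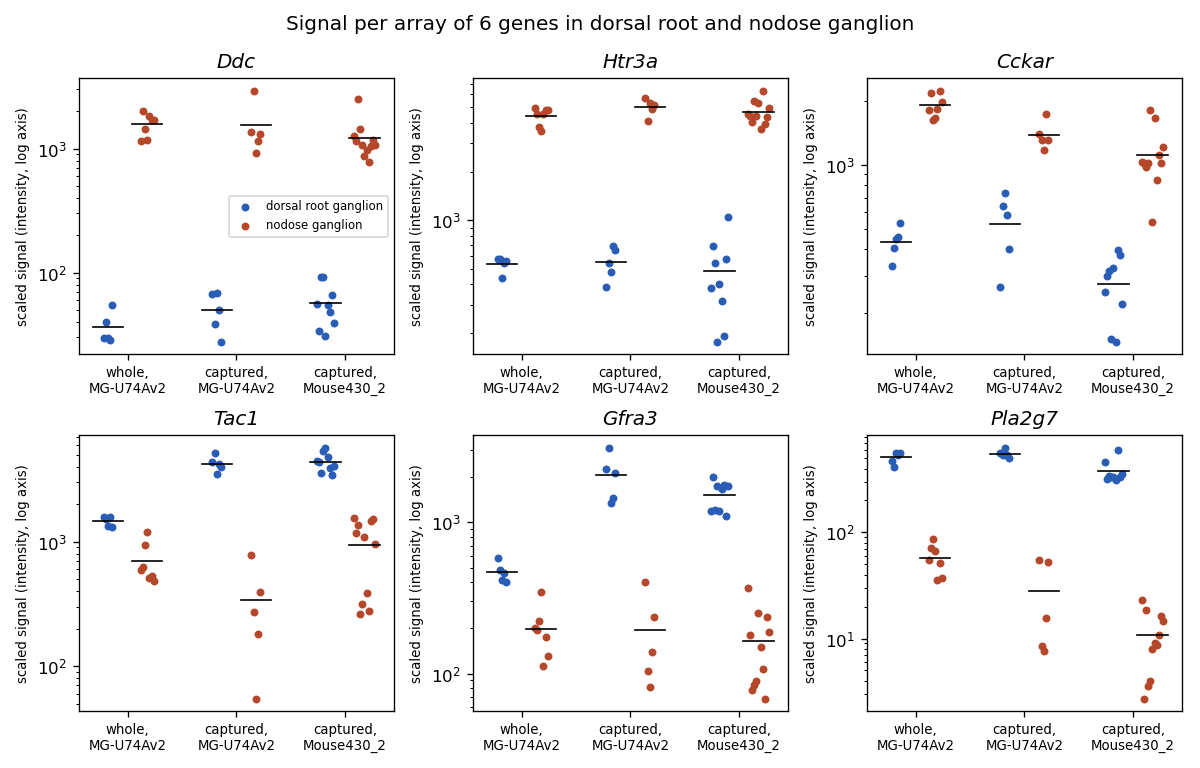
Scaled signal of 6 genes (log axis, intensity units) on each array of whole ganglia and captured neurons, with DRG in blue, NG in red and a line at each group mean. Ddc lies between 28.62 and 54.64 on whole DRG arrays and between 1161 and 2020 on whole NG arrays, while Tac1 lies between 482.9 and 1200 in whole NG and between 54.66 and 787.3 in captured NG neurons on MG-U74Av2.

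The second comparison asked how captured visceral neurons of NG differed from those of DRG on MG-U74Av2. Ntsr1 was 35.5-fold higher in NG, at 936.7 ± 275.8 against 14.8 ± 2.448 (SD, n = 5 each; log2 difference 5.15, SE 0.2, adjusted p = 3.18e-10). Cavin2 (27.4-fold), Gpr65 (25.1-fold), Ddc (24.1-fold), the mannosidase Man1a (16-fold), the formin Fhod3 (14.2-fold), the drug efflux pump Abcb1a (13.7-fold) and Tes (11.4-fold) followed, and Htr3a was 9.15-fold higher (5026 ± 592.5 against 548 ± 124.3). DRG neurons held more Grik1, at 632.1 ± 358.2 against 13.04 ± 9.689 (log2 difference -4.68, SE 0.33, adjusted p = 1.94e-07), more of the sodium channel Scn1a, at 802.1 ± 163 against 26.31 ± 8.1 (-4.46, SE 0.192), and more Tac1, at 4238 ± 614.1 against 337.8 ± 280.3 (-4.03, SE 0.464). The proteoglycan gene Vcan (-4.21, SE 0.536), Pla2g7 (-4.08, SE 0.33), Aqp1 (-3.89, SE 0.367), and the secreted Wnt antagonist Frzb (-3.81, SE 0.262) were also higher in DRG neurons. The groups did not overlap for any gene named so far in this comparison, again a requirement for those named for the largest differences. Among the 1652 probe sets past the threshold, 1132 showed no overlap. For Scn10a the difference was 0.02 (SE 0.099, adjusted p = 0.928), at signals of 5096 ± 618.5 in NG and 5023 ± 450.5 in DRG.

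Of 9 large-diameter afferent genes, 5 were higher in DRG (7 when adjusted over the list alone) and 0 in NG, with the neurofilament genes Nefm (-2.06, SE 0.19) and Nefh (-2.05, SE 0.096) at the top. Of 7 neurotrophic factor receptors, 5 were higher in DRG and 0 in NG: Gfra3 (-3.48, SE 0.354), Osmr (-2.32, SE 0.358) and the neurotrophin-3 receptor Ntrk3 (-1.67, SE 0.305) led them. The small-diameter nociceptor list had 5 of 8 higher in DRG and 0 in NG (2 in NG when adjusted over the list alone). Of 5 genes in the list of sodium channels and their intracellular FGF partners, 2 were higher in DRG (3 over the list alone), Scn1a with the larger difference. Adjusted p with an estimated correlation was 0.155, 0.155, 0.361 and 0.155 for these 4 lists, against 4.86e-05, 0.00287, 0.0262 and 0.0182 with the preset one; the large-diameter list reached 0.0221 when all 4 groups on this array type were fitted together. Kcna1, a potassium channel subunit (-2.88, SE 0.417), the homeobox factor Hmx1 (-2.66, SE 0.296) and the neuropeptide Y receptor Npy2r (-2.52, SE 0.247) were also higher in DRG neurons. Of 8 factors of the epibranchial placode and visceral reflex circuits, 2 were higher in NG, Tbx3 (3.11, SE 0.21) and Tlx2 (1.06, SE 0.177). In DRG 1 was higher, Sox2 (-1.63, SE 0.277), which is also in the list of satellite glia and Schwann cells. Its difference therefore need not lie in the neurons. Camera gave the list of placode and reflex factors an adjusted p of 0.61 with an estimated correlation. Gria2 (2.18, SE 0.177), the prostaglandin receptor Ptger4 (1.57, SE 0.172) and Cckar (1.45, SE 0.231) were higher in NG neurons. Of 13 ribosomal protein genes, 6 were higher in DRG and 0 in NG (adjusted p = 0.361 with an estimated correlation, 0.0082 with the preset one). Subunits of the mitochondrial respiratory chain went both ways here. Uqcrc1 (0.67) and Sdha (0.62) were higher in NG neurons. Cox7b was higher in DRG neurons (-1.65, SE 0.191, in the fit of all 4 groups on this array type). These examples were chosen after their values were seen. Of 13 genes of satellite glia and Schwann cells, 4 were higher in DRG samples and 0 in NG, with the gap junction gene Gja1 at 1035 ± 138.5 against 224.6 ± 116 (-2.28, SE 0.274) and S100b at -1.59 (SE 0.166); adjusted p = 0.61 with an estimated correlation. H2-Aa was higher in NG samples (2.29, SE 0.239).

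Limma called 792 probe sets higher in NG neurons and 860 higher in DRG neurons, 21.8% of those tested, of which 184 and 363 differed by at least 2-fold. With the Gapdh ratio as a covariate the NG count was 514. NG took 47.9% of the calls, and 46% and 50.7% under the other scalings.

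The third comparison repeated the contrast between captured NG and DRG neurons on Mouse430_2, with 11 and 9 samples. Ltk, a receptor tyrosine kinase, was 67.6-fold higher in NG neurons, at 1354 ± 170.8 (SD, n = 11) against 14.89 ± 11.54 in DRG neurons (SD, n = 9; log2 difference 6.08, SE 0.212, adjusted p = 1.27e-17). Ntsr1 was 42.7-fold higher, the doublecortin-domain gene Dcdc2a 40.8-fold, the gastrin-releasing peptide gene Grp 38.3-fold, the cilium-associated gene Cfap52 24.6-fold, the mechanosensitive channel Piezo1 20.3-fold, Cavin2 19.5-fold and Ddc 19.1-fold. DRG neurons held 53.3-fold more Hoxa9 (697.2 ± 350 against 4.792 ± 3.358, log2 difference -5.74, SE 0.23, adjusted p = 2.51e-16) and 40.9-fold more Tmem45b (1452 ± 364.7 against 39.91 ± 54.81, -5.36, SE 0.304). Pla2g7, the adenylyl cyclase Adcy7 and Tmem255a, at 21.7-fold each, Vcan at 21-fold, the homeobox factor Hmx1 at 18.7-fold and Aqp1 at 17.2-fold were also higher in DRG neurons. For all of these genes the groups did not overlap, as the rule required of those named for the largest differences. Among the 6250 probe sets past the threshold, 1080 showed no overlap.

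Among receptors and channels, NG neurons held more of both 5-HT3 subunits, Htr3a (10.9-fold, 4674 ± 778.5 against 481.3 ± 274.7) and Htr3b (8.95-fold), and of the ATP-gated channel subunits P2rx2 (7.52-fold) and P2rx3 (1.93-fold, 4095 ± 641.5 against 2121 ± 387.6). The nicotinic subunits Chrna5 (log2 difference 3.04, SE 0.22), Chrna3 (1.51, SE 0.184) and Chrnb4 (1.31, SE 0.221) were higher in NG neurons, and 4 of 11 acetylcholine receptor genes were higher there against 2 in DRG (3 over the list alone; adjusted p = 0.759 with an estimated correlation). Cckar (1.99, SE 0.198), the neuropeptide gene Vip (2.72, SE 0.261), the BDNF receptor Ntrk2 (2.29, SE 0.135), Scn3b (1.37, SE 0.113) and Kcnh2 (1.40, SE 0.167) were higher in NG neurons as well. DRG neurons held more of the irritant receptor Trpa1 (-2.71, SE 0.311), the capsaicin receptor Trpv1 (1648 ± 450.9 against 474.7 ± 147.5, -1.80, SE 0.187), the acid-sensing channel Asic3 (-2.79, SE 0.309), the touch channel Piezo2 (-2.38, SE 0.262), Scn4b (-3.82, SE 0.228) and Kcna1 (-3.23, SE 0.156). The CGRP gene Calcb (5194 ± 728.6 against 497 ± 446.8, -3.73, SE 0.311), Tac1 (-2.49, SE 0.306), Gfra3 (-3.30, SE 0.243), Ntrk3 (-2.96, SE 0.269) and Gfra1 (-1.85, SE 0.235) were higher in DRG neurons too. No difference was called for Scn10a (-0.04, SE 0.16, adjusted p = 0.89) or for Ret (-0.03, SE 0.127, adjusted p = 0.914). Ntrk2 was read by 7 probe sets, of which 2 besides the one given were called in the same direction, and Ntrk3 by 6, again with 2 others called in the same direction. The remaining ones were not called.

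On Mouse430_2, developmental factors went both ways. Of 9 measured factors of the epibranchial placode and visceral reflex circuits, 5 were higher in NG neurons and 1 in DRG neurons, with Tbx3 (3.32, SE 0.216), Eya1 (2.88, SE 0.248) and Phox2a (2.18, SE 0.251), a determinant of autonomic and visceral neurons, at the top; adjusted p = 0.228 with an estimated correlation and 0.0238 with the preset one. The DRG-higher one was Sox2 (-1.06, SE 0.207), which is also in the list of satellite glia and Schwann cells. It was not called among the sample numbers absent from MG-U74Av2 (limma adjusted p = 0.09), a smaller fit of 6 NG and 4 DRG samples. Whether its difference came from neurons or from glia in the samples was not tested. Of 13 factors of somatosensory neurons from the neural crest, 6 were higher in DRG neurons, led by Hmx1 (-4.23, SE 0.309), Prrxl1 (-3.28, SE 0.16) and Pou4f1 (-2.26, SE 0.181), and 5 in NG neurons (adjusted p = 0.349 with an estimated correlation). Runx1, a factor of nociceptor differentiation, was higher in DRG neurons (-1.82, SE 0.409, adjusted p = 0.00152), where 1 of its 3 other probe sets was also called.

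Of the 33 lists, 2 were called on Mouse430_2 with an estimated correlation. Large-diameter afferent genes had 8 of 10 members higher in DRG neurons and 0 in NG neurons, among them Nefh (4174 ± 929.6 against 1356 ± 234.9, log2 difference -1.60, SE 0.128); the list's adjusted p was 0.00197. Small-diameter nociceptor genes had 10 of 16 higher in DRG neurons (11 when adjusted over the list alone), led by Tmem45b and Gfra3, and 4 higher in NG neurons, P2rx3 among them; the adjusted p was 0.0135, and 0.0815 with the same median on every array. Of 45 potassium and HCN channel genes, 20 were higher in DRG neurons (21 over the list alone) and 6 in NG neurons. That list had an adjusted p of 0.168 with an estimated correlation, 0.000266 with the preset one, 0.0101 with the same median on every array and 0.0459 without NG array 005. Of 14 genes in the list of sodium channels and their intracellular FGF partners, 7 were higher in DRG neurons (8 over the list alone) and 3 in NG neurons (adjusted p = 0.228 with an estimated correlation, 0.0245 with the preset one). Mitochondrial respiratory chain genes had 14 of 42 higher in NG neurons (16 over the list alone), Uqcrc1 among them (0.86, SE 0.118), and 2 in DRG neurons (adjusted p = 0.423 with an estimated correlation, 0.0121 with the preset one).

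Glial markers differed here as well. Of 18 genes of satellite glia and Schwann cells, 8 were higher in the DRG samples (9 over the list alone) and 0 in the NG samples, with S100b at 3125 ± 665.8 against 1344 ± 282.7 (-1.22, SE 0.133) and Gja1 at -1.15 (SE 0.294); adjusted p = 0.211 with an estimated correlation and 0.0238 with the preset one. For Gja1 the difference was -0.22 (adjusted p = 0.611) among the samples whose numbers were absent from MG-U74Av2. The VEGF receptor Kdr (2.44, SE 0.259) was higher in NG samples, although 5 of 16 endothelial and mural genes were higher in DRG samples and 2 in NG samples (adjusted p = 0.479 with an estimated correlation). Limma called 2733 probe sets higher in NG neurons and 3517 higher in DRG neurons, 22.2% of those tested, of which 656 and 1454 differed by at least 2-fold. NG took 43.7% of the calls, 49.8% after quantile normalization (3204 against 3226) and 63.5% with the same median on every array (3845 against 2210), which shifted the median of all probe sets by 0.136.

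**Figure D2:**
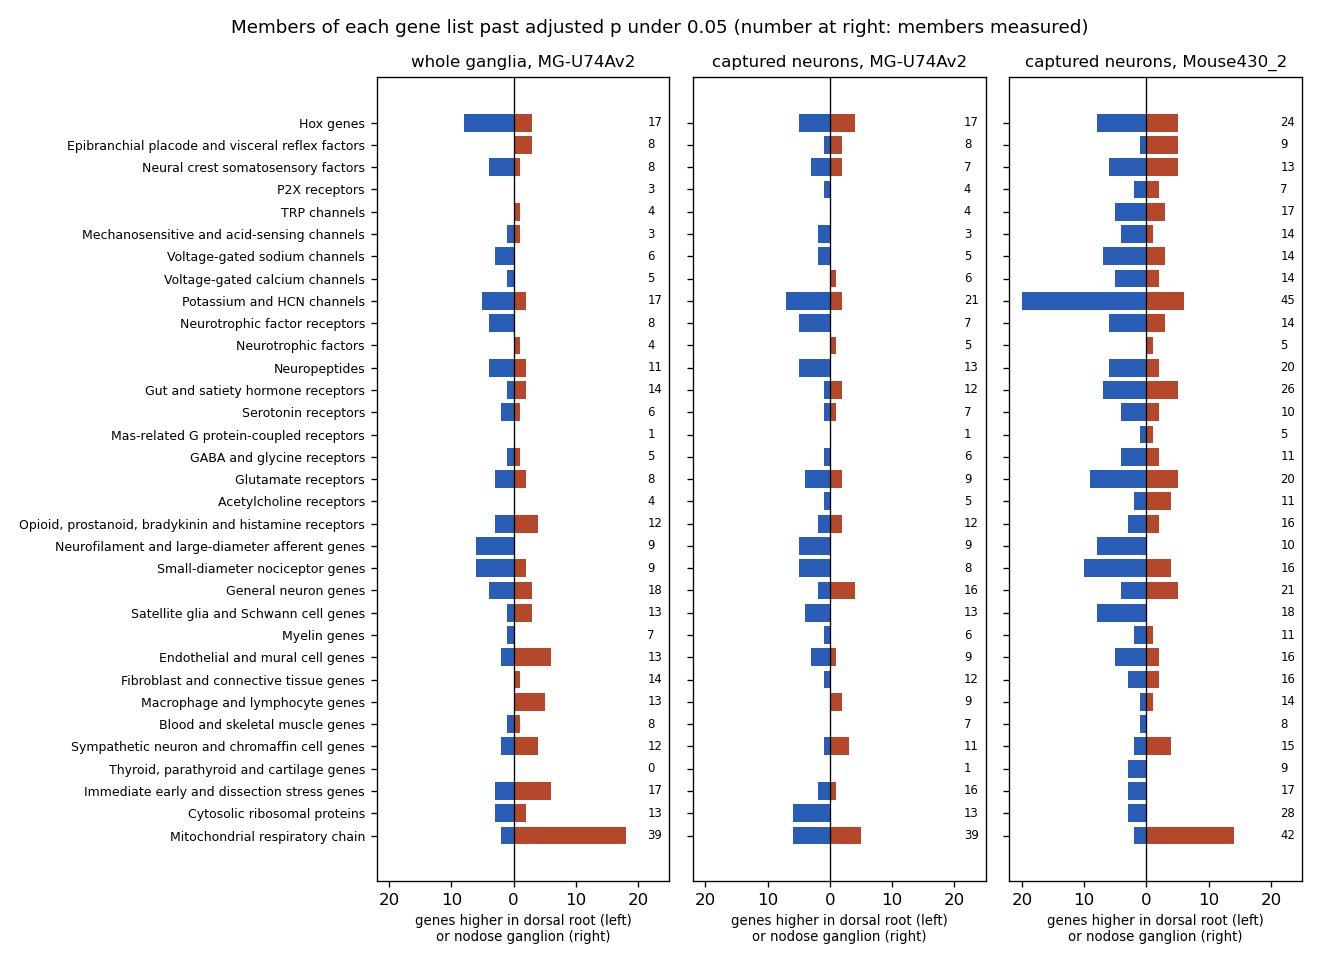
Number of measured members of each of the 33 gene lists past the threshold in each experiment, with genes higher in DRG drawn left of 0 in blue, genes higher in NG drawn right in red, and the number of measured members at the right edge. Potassium and HCN channels on Mouse430_2 show 20 members on the DRG side and 6 on the NG side, and the mitochondrial respiratory chain in whole ganglia shows 2 and 18.

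Hox genes, which mark position along the body axis during development, differed in both directions in all 3 experiments. Hoxb5 was higher in NG by 3.11 (SE 0.113) in whole ganglia, at 3263 ± 567.1 against 363.3 ± 29.13, by 3.24 (SE 0.153) in captured neurons on MG-U74Av2 and by 3.02 (SE 0.111) on Mouse430_2. Hoxb4 was higher in NG by 2.03, 2.40 and 3.15 and Hoxb6 by 1.15, 1.37 and 2.28. In contrast, Hoxd1 was higher in DRG in each experiment (-2.27, -3.63 and -3.05), as was Hoxd8 (-1.51, -1.46 and -2.40). Hoxa7 was higher in DRG in both experiments on MG-U74Av2 (-2.74, SE 0.163, and -3.69, SE 0.189), and Hoxd9 on Mouse430_2 (-2.98, SE 0.246). Hoxa9 differed by -1.46 (SE 0.196) in whole ganglia, by -0.64 (SE 0.234, adjusted p = 0.0638, and 0.0305 when all 4 groups were fitted together) in captured neurons on MG-U74Av2 and by -5.74 (SE 0.23) on Mouse430_2. Of 17 measured Hox genes, 3 were higher in NG and 8 in DRG in whole ganglia. The counts were 4 and 5 of 17 in captured neurons on MG-U74Av2, and 5 and 8 of 24 on Mouse430_2. Camera, which looks for a shift in 1 direction, gave adjusted p = 0.683, 0.98 and 0.759 with an estimated correlation.

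**Figure D3:**
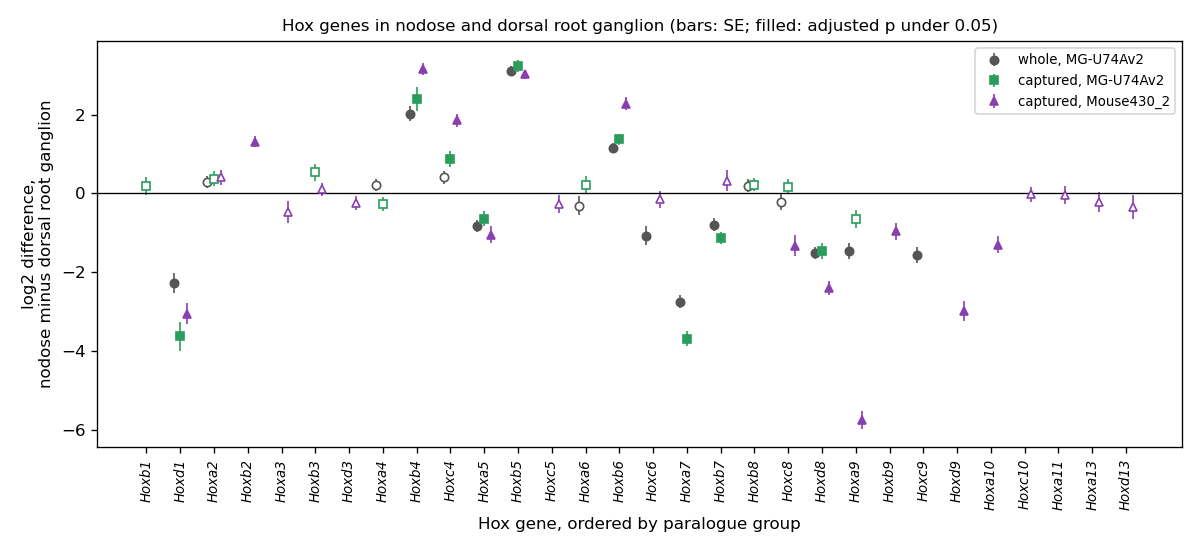
Log2 difference (NG minus DRG) of each measured Hox gene, ordered by paralogue group, with its SE as a bar; circles are whole ganglia, squares captured neurons on MG-U74Av2 and triangles captured neurons on Mouse430_2, filled where adjusted p was under 0.05. Hoxb5 lies at 3.11, 3.24 and 3.02, and Hoxa9 reaches -5.74 on Mouse430_2.

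Across genes, which are not independent replicates, the ganglion differences were compared between experiments. Between the captured-neuron experiments, Pearson's r was 0.731 (Spearman's rho 0.604) over 5331 genes. Of 766 genes called in both, 376 were higher in NG in both, 381 higher in DRG in both, and 9 had opposite directions, so that 98.83% went the same way; independent lists of these lengths would share 104 and 95.6. Whole ganglia and captured neurons on MG-U74Av2 gave r = 0.478 (rho 0.306) over 5544 genes, with 282 NG-higher and 274 DRG-higher in both (128 and 117 for independent lists) and 131 in opposite directions. Whole ganglia and captured neurons on Mouse430_2 gave r = 0.508 (rho 0.373) over 5465 genes, with 403 and 328 in the same direction (196 and 141 for independent lists) and 116 in opposite directions. Among 5176 genes measured in all 3 experiments, 209 were called higher in NG in all 3 and 195 higher in DRG in all 3. The former included Ddc (5.04, 4.59 and 4.26), Ntsr1 (3.91, 5.15 and 5.42), Cavin2 (3.09, 4.77 and 4.28) and Htr3a (3.02, 3.19 and 3.44). The latter included Pla2g7 (-2.95, -4.08 and -4.44), Grik1 (-2.78, -4.68 and -3.97) and Aqp1 (-2.75, -3.89 and -4.11).

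Captured-neuron arrays of the 2 array types that carry the same sample number deviated together from their group means. Across genes, r between same-numbered arrays was 0.204 to 0.325 in DRG (mean 0.271) and 0.404 to 0.468 in NG (mean 0.445), while the highest r between different numbers was 0.206 and 0.221. All 5 DRG and all 5 NG arrays on MG-U74Av2 correlated best with the Mouse430_2 array of their own number (exact one-sided p = 6.6e-05 and 1.8e-05, the smallest these designs can give). Restricting Mouse430_2 to the 6 NG and 4 DRG samples whose numbers were absent from MG-U74Av2, r was 0.618 over 5378 genes, and of 513 genes called in both, 248 and 249 went the same way and 16 the opposite way.

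**Figure D4:**
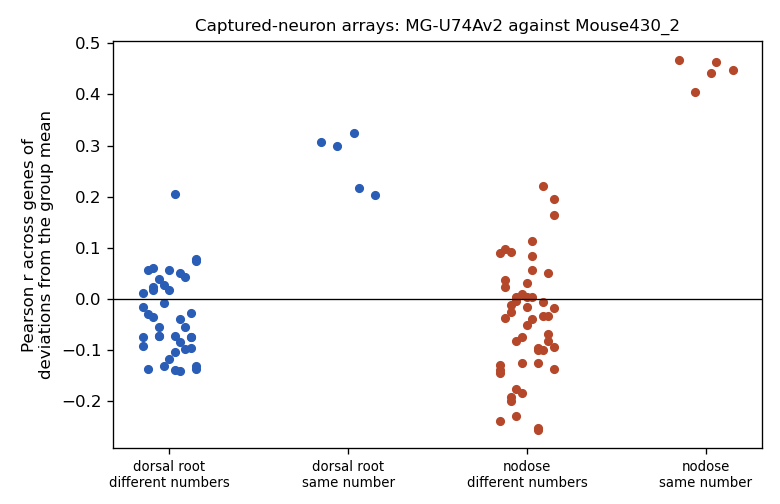
Pearson's r across genes (vertical axis, no unit) between the deviations from the group mean of each captured-neuron array on MG-U74Av2 and each on Mouse430_2, for arrays of different and of the same sample number in DRG (blue) and NG (red). Pairs with the same number lie between 0.204 and 0.325 in DRG and between 0.404 and 0.468 in NG, and pairs with different numbers reach at most 0.206 and 0.221.

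The captured neurons and the whole ganglia on MG-U74Av2 were then compared within each ganglion. Ogn, an extracellular matrix proteoglycan, fell from 423.7 ± 108.2 to 32.43 ± 15.21 in captured DRG neurons (SD, n = 5 each; log2 difference -3.35, SE 0.364) and differed by -3.10 in NG (SE 0.337), while the collagen gene Col3a1 differed by -2.65 and -2.96 and Lum by -2.24 and -2.97. Of 14 fibroblast and connective tissue genes, 9 were lower in captured neurons and 0 higher in DRG, and 12 and 0 in NG; adjusted p = 0.464 and 0.185 with an estimated correlation, and 0.000197 and 0.000177 with the preset one. The myelin protein gene Mbp (-2.57, SE 0.174, in DRG and -2.44, SE 0.161, in NG) and Egr2, a factor of myelinating Schwann cells (-3.01 and -2.84), were lower, as were 5 of 7 myelin genes in each ganglion, against 1 higher in DRG and 0 in NG. A second, dimmer probe set of Mbp was not called (0.13, SE 0.173, and 0.33, SE 0.16). Sparc, a matrix protein counted among the glial genes, differed by -2.99 (SE 0.187) and -2.92 (SE 0.173). Not every glial gene fell in both ganglia. Gja1 differed by 0.21 in DRG (SE 0.24, adjusted p = 0.502) and by -2.16 in NG (SE 0.222). Sox2 differed by -1.79 (SE 0.199) in DRG and -4.27 (SE 0.184) in NG, and the endothelial cadherin Cdh5 by -0.81 and -3.28; the DRG value of Cdh5 was no longer called with the Gapdh ratio as a covariate (-1.10, adjusted p = 0.0627). General neuron genes went both ways, 7 up and 7 down of 18 in DRG (9 down over the list alone) and 8 up and 6 down in NG. Gap43, a growth-associated protein of axons, was higher in captured neurons (1.02, SE 0.106, and 0.47, SE 0.098), whereas the synaptic vesicle gene Syp (-2.29, SE 0.183, and -2.55, SE 0.17) and Uchl1 (-1.10, SE 0.111, and -0.95, SE 0.103) were lower.

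The 4 groups were fitted together on 8309 probe sets. In DRG, 1903 were higher and 2017 lower in captured neurons, and in NG 2175 and 2424. The preparations also differed in experiment, RNA amplification and the Gapdh 3 prime over 5 prime log2 ratio, which was 5.33 ± 0.12 and 5.50 ± 0.45 in whole DRG and NG and 6.96 ± 0.38 and 6.63 ± 0.25 in captured neurons. With that ratio as a covariate, the totals of 3920 and 4599 became 1348 and 2958.

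The last comparison asked which ganglion differences themselves differed between captured neurons and whole ganglia. For Scn1a the difference was -0.73 (SE 0.184) in whole ganglia, at 476.6 ± 175.7 in NG and 770.7 ± 125 in DRG, and -4.44 (SE 0.199) in captured neurons, an interaction of -3.72 (SE 0.271, adjusted p = 5.43e-10). Npy2r was at 2280 ± 958.6 in whole NG and 347.7 ± 140.6 in captured NG neurons, with an interaction of -3.18 (SE 0.417). Tac1 (-2.90, SE 0.531), Kcna1 (-2.43, SE 0.443) and Nefh (-1.46, adjusted p = 2.25e-09) likewise stood further toward DRG in captured neurons. In the opposite direction, Man1a was more NG-higher in captured neurons (2.76, SE 0.361), and the DRG excess of Mobp in whole ganglia was smaller in captured neurons (3.53, SE 0.629). There, 4 of 5 DRG arrays lay between 2.619 and 5.116 and array 003 at 156; the interaction was called with and without that array. Sox2 was higher in NG in whole ganglia (0.87, SE 0.184) and higher in DRG in captured neurons (-1.61, SE 0.199; interaction -2.48, adjusted p = 5.24e-07). The interaction was called for 1512 probe sets, 641 toward NG and 871 toward DRG. Of these, 1061 had opposite signs in the 2 preparations, 177 of them called in both, and 451 had the same sign, 300 of them with the larger difference in captured neurons. Without NG array 073 the count was 1543. Of 39 mitochondrial respiratory chain genes, 10 moved toward DRG and 2 toward NG (adjusted p = 0.921 with an estimated correlation), and of 13 satellite glia and Schwann cell genes, 5 moved toward DRG and 0 toward NG (adjusted p = 0.679).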

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

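In this part, the test of brightness and RNA degradation on array 073 was chosen only after the result was seen. Array 073 itself was picked for its place on the first principal component. Its Hox test was therefore also set up after that was seen, though before its own outcome. Whether other groupings of the arrays gave as many calls was asked of each comparison with 100 splits, the real one included. Only the real split, 1 of 100, reached the real count in each case, so a chance arrangement of the arrays is unlikely. The splits do not tell what sets the groups apart, and the samples of a group may be technical replicates. In whole ganglia it called 2727 probe sets and the highest other split called 1530; that split exchanged 5 arrays, so that it set 5 NG arrays against all 5 DRG arrays and the remaining 2 NG arrays. In captured neurons the real counts were 1652 on MG-U74Av2 and 6250 on Mouse430_2, and the highest other count was 1 in both. For captured against whole, fitted on the arrays of 1 ganglion, the counts were 4381 in DRG (highest other 1) and 4218 in NG (highest other 910, again with 5 arrays exchanged). For the interaction, 1512 stood against at most 1 when residuals of the additive model were permuted.

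Whole NG array 073 lay at 7.1 on the first principal component (48.5% of the variance), between the other 6 NG arrays (16.6 to 24) and the DRG arrays (-27.8 to -24.9). Its estimated DRG share was 0.177 over 188 probe sets higher in DRG and 0.357 over 225 higher in NG. Admixture of DRG tissue like that on the DRG arrays would bring posterior Hox transcripts at the same share. The median over 5 probe sets of Hoxa7, Hoxa9, Hoxc9 and Hoxd8 was -0.024, below the 5th percentile of 10000 random sets of that size (0.025). That argues against admixture of such tissue. The Gapdh ratio of array 073 was 5.522 and its trimmed mean 254.2. Both lay inside the ranges of the other NG arrays (4.867 to 6.02 and 174.9 to 408.3), which argues against degradation or brightness. Admixture of crest-derived sensory neurons that lack posterior Hox expression, for which 0.025 was the bound, may explain the array, a hypothesis resting on 1 array and 5 probe sets. The same comparison gave both readings, so DRG tissue low in posterior Hox transcripts cannot be told apart from such neurons. A real difference of that sample's ganglion was not tested.

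In 31 of 335 groups of 4 to 10 arrays, 1 array stood apart from the rest. This was measured as its gap to the nearest array over the whole range. The bound used gives about 1 in 20 by chance if values are normally distributed. Gene signals were taken here on a linear scale and the groups reuse the same arrays, so an excess over chance is not shown. Of the 31, 2 were array 073. In whole DRG these were Syt17 (gap 0.81 of the range, array 019 at 25.1 against 8.363), Htr3a (0.7495, array 019 lowest at 437.4 against 540.9), Hoxb4 (0.758, array 070 at 17.57 against 8.648), Hspa1b (0.83, array 037 at 412.1 against 247), Acta1 (0.779, array 070 at 203.6 against 111.9), Gap43 (0.839, array 026 at 2668 against 2166) and the trimmed mean (0.892, array 037 at 344.5 against 292.3). In whole NG they were Ly86 (0.6002, array 073 at 56.6 against 35.06), Scn1a (0.758, array 073 at 863.9 against 465.9), Adcy8 (0.572, array 026 at 219.1 against 183), Rxrg (0.623, array 036 lowest at 24.99 against 42.11) and the trimmed mean (0.66, array 039 at 408.3 against 254.2). On MG-U74Av2, captured DRG neurons had Grik1 (0.711, array 010 at 1241 against 590.2), Aqp1 (0.93, array 006 at 902.3 against 542.8), Cdh5 (0.791, array 014 at 105.3 against 63.28), Egr2 (0.714, array 003 lowest at 9.499 against 56.67) and Mobp (0.984, array 003 at 156 against 5.116). Captured NG neurons there had Ddc (0.774, array 003 at 2919 against 1373), Vcan (0.725, array 010 at 307.2 against 96.44), Frzb (0.851, array 010 at 26.69 against 10.42), Hoxb5 (0.718, array 014 at 3306 against 2584), Hoxa9 (0.773, array 007 lowest at 14.23 against 31.44), Egr2 (0.74, array 014 at 121.4 against 71.74) and Jun (0.789, array 014 at 196.6 against 131.8). On Mouse430_2 only the DRG group was tested, since the NG group holds 11 arrays, and it had Grp (0.742, array 008 at 18.9 against 7.354), Tmem45b (0.674, array 010 at 2364 against 1539), Aqp1 (0.543, array 006 at 1546 against 1082), Chrna5 (0.601, array 005 at 18.29 against 8.346), Hoxd8 (0.587, array 011 at 338.2 against 226.9), Sox2 (0.4933, array 003 lowest at 16.93 against 26.62) and Adcy8 (0.509, array 005 at 198.8 against 132.6).

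For 47 of the 68 named genes tested, the ganglion difference itself differed between captured neurons and whole ganglia on MG-U74Av2 (limma interaction, 22 arrays). That share does not describe all genes, since many of these were named for large differences within an experiment, and Adcy8, Rxrg, Prss12 and Itgav after their opposite directions were seen. Over all 8309 probe sets tested, 1512 (18.2%) were called. Toward NG in captured neurons moved Mobp (log2 3.53), Adcy8 (2.86), Man1a (2.76), Tes (1.98), Cavin2 (1.68), Abcb1a (1.65), Prkcq (1.53), Tbx3 (1.40), Fhod3 (1.30), Ntsr1 (1.20), H2-Aa (1.16) and Scn10a (0.56). Toward DRG moved Scn1a (-3.72), Npy2r (-3.18), Tac1 (-2.90), Kcna1 (-2.43), Gfra3 (-2.22), Hmx1 (-2.20), Grik1 (-1.88), Trpc4 (-1.87), Nefm (-1.73), Crhr2 (-1.62), Ntrk3 (-1.53) and Nefh (-1.46). Further genes that moved toward DRG were Rxrg (-3.57), Itgav (-3.13), Prss12 (-2.64), Sox2 (-2.48), Gja1 (-2.37), Vcan (-2.35), Frzb (-2.06), Eng (-1.91), Jun (-1.87), Fos (-1.45), Myl1 (-1.15), Atp5o (-0.93), Ier2 (-0.83), S100b (-0.76) and Ndufa9 (-0.76). Less firm were Gna14 (0.97, but -0.03 with no pseudocount), Ptger4 (0.77), Gria2 (0.67), Pla2g7 (-1.10), Hoxd1 (-1.26), C1qa (-1.42), Uqcrq (-0.83) and Hoxa7 (-0.90). Each of these lost its call under other settings or with single arrays left out. The cells collected, the RNA amplification and the experiment changed together, so no explanation of these was tested.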

How the results depend on the processing

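In this part, the fit of only the sample numbers absent from MG-U74Av2 was chosen after the data were seen. Requiring at least 2-fold left 198 NG-higher and 160 DRG-higher probe sets in whole ganglia, 184 and 363 in captured neurons on MG-U74Av2, 656 and 1454 on Mouse430_2, 646 for the interaction, and 1138 (DRG) and 1386 (NG) for captured against whole. That follows from the stricter threshold. With the Gapdh ratio as a covariate, the NG-higher count on MG-U74Av2 was 514, and captured against whole gave 1348 in DRG and 2958 in NG; that ratio differs between the preparations, so the covariate takes up part of the latter contrast. With the same median on every array, 2210 probe sets were DRG-higher on Mouse430_2; the cause was not tested. Apart from the replicate block, the other settings kept each of these counts within 1.5 times its value.

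The sample number as a fixed replicate block gave 465 NG-higher probe sets on MG-U74Av2, and 1708 NG-higher and 2317 DRG-higher on Mouse430_2; fewer samples carry a number found in both ganglia. As a random block it gave 774 and 842, and 2793 and 3591. Same-numbered NG and DRG arrays showed no shared deviation. On MG-U74Av2 r ran from -0.106 to 0.111 over 4 pairs (exact one-sided permutation p = 0.65). On Mouse430_2 it ran from -0.154 to 0.155 over 7 pairs (exact one-sided permutation p = 0.47). In each experiment 1 array correlated best with its own number. Ganglia of the same animal need not deviate together, so whether a number stands for 1 animal in both ganglia stays open.

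Leaving out each array in turn gave 1283 to 1600 NG-higher and 1039 to 1304 DRG-higher probe sets in whole ganglia, 629 to 776 and 691 to 861 on MG-U74Av2, and 2507 to 2796 and 3090 to 3559 on Mouse430_2. The interaction ran from 1318 to 1543, and captured against whole from 3596 to 4065 in DRG and from 4351 to 4662 in NG.

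Of the values of named genes under alternatives other than leaving out an array, 2854 kept direction and side of the threshold, 61 lost the call, 20 gained it and 1 reversed: the Gna14 interaction was -0.03 (adjusted p = 0.978) with no pseudocount, against 0.97 (adjusted p = 0.0435); the cause was not tested. With an array left out, 4355 were kept, 66 lost the call and 17 gained it. Apart from the 2-fold requirement, the losses were interactions of Gna14, Gria2, Pla2g7, Ptger4, Hoxd1, Hoxa7, C1qa and Uqcrq, the captured-against-whole values of Cdh5 and Mapt in DRG, Tnnc2 in whole ganglia, and Gja1, Itgav and Sox2 on Mouse430_2. The gains were interactions of Cckar, Aqp1, Baiap2l1, Ly86, Hoxa9, Hspa1b and Tlx2, and the ganglion differences of Acta1 in whole ganglia and Hoxa9 on MG-U74Av2. Gja1 on Mouse430_2 differed by -0.22 (adjusted p = 0.611) among the sample numbers absent from MG-U74Av2, where 1964 probe sets were NG-higher and 2398 DRG-higher. For gene lists, 150 values gained a call, 2037 were kept and 1 lost it, the small-diameter nociceptor list on Mouse430_2 with the same median on every array. Of the gains, 57 came from directional and 77 from mixed fry, which test a list against no change rather than against other genes, and 14 from the preset correlation. The others were the large-diameter list on MG-U74Av2 in the joint fit and the potassium and HCN list on Mouse430_2 with the same median on every array. With an array left out, 1 gained a call, the same potassium and HCN list without NG array 005, and 3283 were kept.

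The correlation between experiments moved with the filter: with none it was 0.427, 0.637 and 0.445, and at the 60th percentile 0.789 between the captured-neuron experiments and 0.553 between whole ganglia and Mouse430_2. The cause was not tested. Detection calls were not used, so signals of dim genes may be background.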

Other observations

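In this part, the fit of only the sample numbers absent from MG-U74Av2 and the tests of Hox axial position and of Hox cross-hybridization were chosen only after the result was seen. Some genes went opposite ways in whole ganglia and in captured neurons on Mouse430_2, 116 in all, and these examples were chosen after their values were seen. Adcy8, an adenylyl cyclase, was DRG-higher in whole ganglia (-0.69, SE 0.12) and NG-higher in captured neurons on Mouse430_2 (2.20, SE 0.2) and MG-U74Av2 (2.17). The retinoid receptor Rxrg (0.94, -1.91 and -2.65), the protease Prss12 (0.61, -1.83 and -2.03) and the integrin Itgav (0.63, -1.74 and -2.50) went the other way; for Itgav the Mouse430_2 value was -0.60 (adjusted p = 0.0951) among the sample numbers absent from MG-U74Av2. On MG-U74Av2 their interactions had adjusted p of 2.01e-09 (Adcy8), 1.97e-07 (Rxrg), 2.01e-09 (Prss12) and 1.63e-09 (Itgav).

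Arrays of the captured-neuron experiments with the same sample number deviated together, and all 10 on MG-U74Av2 correlated best with the Mouse430_2 array of their own number. Shared animals were considered before the data were examined, because every sample number on MG-U74Av2 recurs on Mouse430_2. The bound of all 10 was set only after the count was seen. The count shows that same-numbered arrays share a source of deviation. It cannot tell RNA of the same animals or extracts from brightness or 3 prime bias shared by number, so this stays open. The 2 experiments are therefore not taken as independent. After brightness and both control ratios were regressed out, 7 of the 10 still correlated best with their own number, all 5 in NG but 2 of 5 in DRG. The total lies between the bounds set for excluding (8) and keeping (5) array brightness or 3 prime bias shared by number, which stays open. No biological explanation was tested.

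Hox genes called in paralogue groups 7 and above were all DRG-higher, 5 in whole ganglia, 3 in captured neurons on MG-U74Av2 and 6 on Mouse430_2, a division chosen after the values were seen. In groups up to 6 the NG-higher and DRG-higher counts were 3 and 3, 4 and 2, and 5 and 2. The axial level of the ganglia may explain this, but over 24 genes on Mouse430_2 the rank correlation of group with difference was -0.292 (permutation p = 0.17), with -0.419 (p = 0.094) and -0.295 (p = 0.25) in the other experiments, so it stays open. Cross-hybridization between paralogues of the same group would give them the same sign. In whole ganglia 2 groups held called members of opposite sign, which argues against a wholly shared signal there. In each captured-neuron experiment 1 group did, short of the bound of 2. On MG-U74Av2, the array type of the whole ganglia, captured neurons had Hoxb5 at 3.24 and Hoxa5 at -0.64. Hoxd1 was at -3.63 beside Hoxb1 at 0.18 (SE 0.227), and Hoxb4 at 2.40 beside Hoxa4 at -0.27. These values argue against a wholly shared signal for those genes, while Hoxa7 and Hoxb7, and Hoxb4 and Hoxc4, had the same sign. On Mouse430_2, Hoxb5 at 3.02 (SE 0.111) and Hoxa5 at -1.05 (SE 0.22) argue against a wholly shared signal for those 2 genes. Of the 4 groups there with at least 2 called members, only this 1 held opposite signs. The question stays open for the other groups on Mouse430_2, as does a partly shared signal in every experiment.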
